A study of Mus musculus with 20 samples.

How the data were processed

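Gene expression was measured in total RNA from mouse proximal colon organoids on 20 single-colour (Cy3) Agilent arrays, 1 array per organoid type, line and medium. Per the labels, organoids came from male mice heterozygous for a Cre-activable BrafV600E allele. EV organoids received the lentiviral backbone alone. BRAF organoids received Cre and were profiled 5 months after induction. Selected organoids were BrafV600E organoids selected for growth in base medium, which lacks stem-cell niche factors. Each culture, the organoids of 1 type and line, was profiled after 48 h in base medium and after 48 h in the medium that the labels name ENSW, so it gave 2 arrays. Per the labels' protocols, the culture medium held Wnt3a, R-spondin and Noggin conditioned media and EGF. EV, BRAF and selected organoids had 3 lines each, all in both media, which gave 6 groups of 3 arrays. Wild-type organoids gave 1 array per medium.

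The scanner output held fluorescence intensity per spot, extracted per the file headers with Feature Extraction 10.7.3.1. The processed signal used here was the background-subtracted intensity per the file headers. The authors also deposited a table of log2 values for the same arrays. Set against the scanner output, its columns ranked the probes as the median signal without background subtraction did, and its equal distributions across arrays showed quantile normalization. The submitters' processing notes name limma as a tool.

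Each array held 43020 spots other than controls, for 39429 probes. The 1377 control spots and 48 outlier spots were left out, and 0 spots were saturated. Probe names were brought up to date through the RefSeq accession for 26575 probes, through the symbol for 2602 and through an older symbol for 492. The other 9760 probes kept the name in the files. Probe coordinates are those of the files (mm9). The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. Spots of 1 probe were averaged. Probes well above background on at least 3 of the 18 EV, BRAF and selected arrays were kept (26827 probes). The probe with the highest mean stood for each gene, which left 21424 genes, 14828 of them with a gene symbol. All levels are log2 units relative to the 75th percentile of the array. The number of arrays, 3 per group, limits the precision.

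Group means were fitted to the 18 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 12 residual degrees of freedom. There were 12 contrasts, 9 between pairs of groups and 3 tests of whether the response to the medium differed between organoid types. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Differences carry the standard error (SE) of the fit and levels the standard deviation (SD) of 3 arrays. Each p-value rests on the spread between lines over all 6 groups, with media unpaired. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made tables and plots. Where a gene was not well above background on any array of 1 group, the difference is given as "at least N-fold". That bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the array's lowest signal well above background and the probe's own signal. It carries no sampling error and holds for the main processing alone, so it is no floor under other processing. Medians of lists are also given "with bounds", with such genes set to their bound, where that changes them.

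Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 20 lists per contrast. The lists covered colonocyte, goblet, enteroendocrine, tuft and stem cell markers, proliferation, Wnt targets, Wnt antagonists, BMP targets, MAPK output, EGFR ligands, p53 and senescence, fetal-like, gastric, mesenchymal, and blood and endothelial markers, interferon response, cholesterol synthesis, chromatin silencing, and a panel of genes used to type CpG island methylation (CIMP). They held 301 genes, 257 of them measured, and Cdkn2a belonged to both the p53 and CIMP lists. Y-linked genes and Xist formed a further list that was described per array and not tested. The lists, the contrasts, the alternatives and the rule for naming genes were fixed before the data were examined.

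Named genes followed this rule. For each contrast between a pair of groups, the 6 largest rises and 6 largest falls were taken among called genes with a symbol that were well above background on at least 1 array of each group and whose groups did not overlap. Up to 2 genes per direction were added that were not well above background in 1 group, as were up to 4 called members of each list by smallest adjusted p. For the tests of a differing response, the 4 smallest p per direction were taken. Braf, Dusp6, Axin2, Lgr5, Cdx2, Cdkn2a, Krt20, Muc2 and Mki67 were always included. The text prints part of these genes and gives the others as counts. A few other members of the lists are named from the tables of their lists, chosen after their values were seen.

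The labels give each culture a line number, and the same number marks the same line across media and, per the labels, across organoid types. Deviations from the group mean correlated at 0.42 to 0.87 between the 2 media of 1 culture, over 0.1 in 9 of 9 pairs. Between organoid types of the same number in the same medium they correlated at -0.077 to 0.37, over 0.1 in 9 of 18 pairs. The pairing was taken from the labels and not from these correlations, and its block was fitted as an alternative. The arrays lay on 6 slides and were scanned on 1 day. EV and wild-type arrays filled slides 1 and 2, which held no BRAF or selected array. Slide 3 held selected lines 1 and 2, slide 4 held selected line 3 and BRAF line 1, and slides 5 and 6 held BRAF lines 2 and 3. Both media of a culture always shared a slide. Differences between EV and the other organoid types thus cannot be told apart from differences between slides. Slide as a random block does not remove this, and a fixed slide block was not used for these comparisons.

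Counts and named genes were also computed with quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' values and no filter on dim probes. Further fits took the line as a fixed block, the culture or slide as a random block, or left out each array in turn. Counts alone used a 9-array filter, the mean over probes, a fixed slide block, trended and robust eBayes, a 2-fold minimum and only the arrays compared. The lists were also tested by camera with an estimated correlation, fry, quantile normalization and both blocks. The value fry gives tests whether the genes of a list move, on balance, in 1 direction, without setting them against other genes. After the data were seen, selected line 1 and BRAF line 3 were each left out in both media, and each array was left out in turn for the list tests.

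The steps were tested on simulated data made for BRAF against EV organoids in ENSW medium over 21424 genes. Of 100 genes changed by 1 log2 unit, 32% were recovered, and of 100 changed by 3 units, 87%. There were 4 false calls among 123, and the 7 contrasts without a simulated change gave 0 calls. A shifted list was found at an adjusted p of 3.9e-22, and 0 of 20 lists without a shift were called. The simulation did not test correlation between genes or between media of a culture, so it does not bear on the preset correlation. Wild-type arrays were left out of the tests, since there was 1 per medium. Methylation was not analysed here.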

Results

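Transcript levels were compared between EV, BRAF and selected colon organoids, each with 3 lines in ENSW medium and the same 3 lines in base medium. The 18 arrays of these 6 groups and 2 wild-type arrays had 59.6% to 65.2% of their spots well above background. Within a group, arrays correlated across genes at r = 0.944 to 0.988, where genes are not independent replicates. The first principal component held 45.9% of the variance. EV arrays in base medium lay at -193 to -128 on it, and selected arrays at 70.4 to 96.4 in either medium. On the second component, with 12.3%, both arrays of selected line 1 (46.3 and 48.6) lay apart from those of selected lines 2 and 3 (-70.1 to -46.1).

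**Figure D1:**
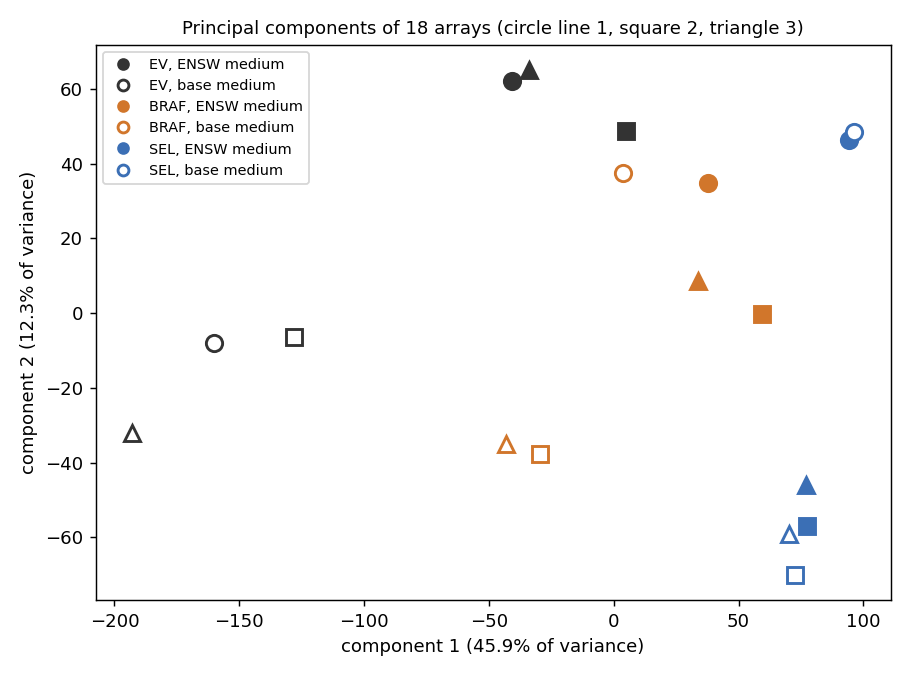
Each point is 1 array placed by its first and second principal component scores (no unit), with 45.9% and 12.3% of the variance, colour for organoid type, filled for ENSW and open for base medium, and shape for line. The 6 selected arrays lie at 70.4 to 96.4 on the first component, while the 3 EV arrays in base medium lie at -193 to -128.

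Braf, the gene that carries the activable allele, lay at -3.37 ± 0.082 (SD, n = 3) in EV organoids in ENSW medium and at -3.03 ± 0.37 in base medium. It lay at -2.34 ± 0.20 and -2.33 ± 0.39 in BRAF organoids and at -2.08 ± 0.32 and -2.26 ± 0.31 in selected organoids, in ENSW and base medium. The wild-type arrays gave -2.16 and -2.31. In ENSW medium Braf was higher by 1.04 ± 0.24 (SE, adjusted p = 0.0233) in BRAF and by 1.29 ± 0.24 (adjusted p = 0.00431) in selected than in EV organoids. In base medium it was higher by 0.71 ± 0.24 (adjusted p = 0.0397) and 0.77 ± 0.24 (adjusted p = 0.0164). The probe (chromosome 6, 39553758 to 39553817, mm9) reads total Braf transcript and does not tell the alleles apart, so it checks nothing about activation. The call for BRAF organoids was lost without any 1 of the 6 arrays in ENSW medium (adjusted p up to 0.0835, without EV line 3) and with normexp (0.0618). In base medium it was lost without EV line 1 or 2 or BRAF line 1 or 3 (up to 0.145, without BRAF line 3), with the authors' values (0.0577) and without a filter (0.0578). The call for selected organoids in base medium was lost without EV line 1 or 2 or selected line 2 (up to 0.075, without selected line 2). Selected and BRAF organoids did not differ beyond the spread between lines (0.25 ± 0.24, adjusted p = 0.794, in ENSW and 0.070 ± 0.24, adjusted p = 0.894, in base medium), and 1 of 2 Braf probes went the other way in ENSW medium.

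**Figure D2:**
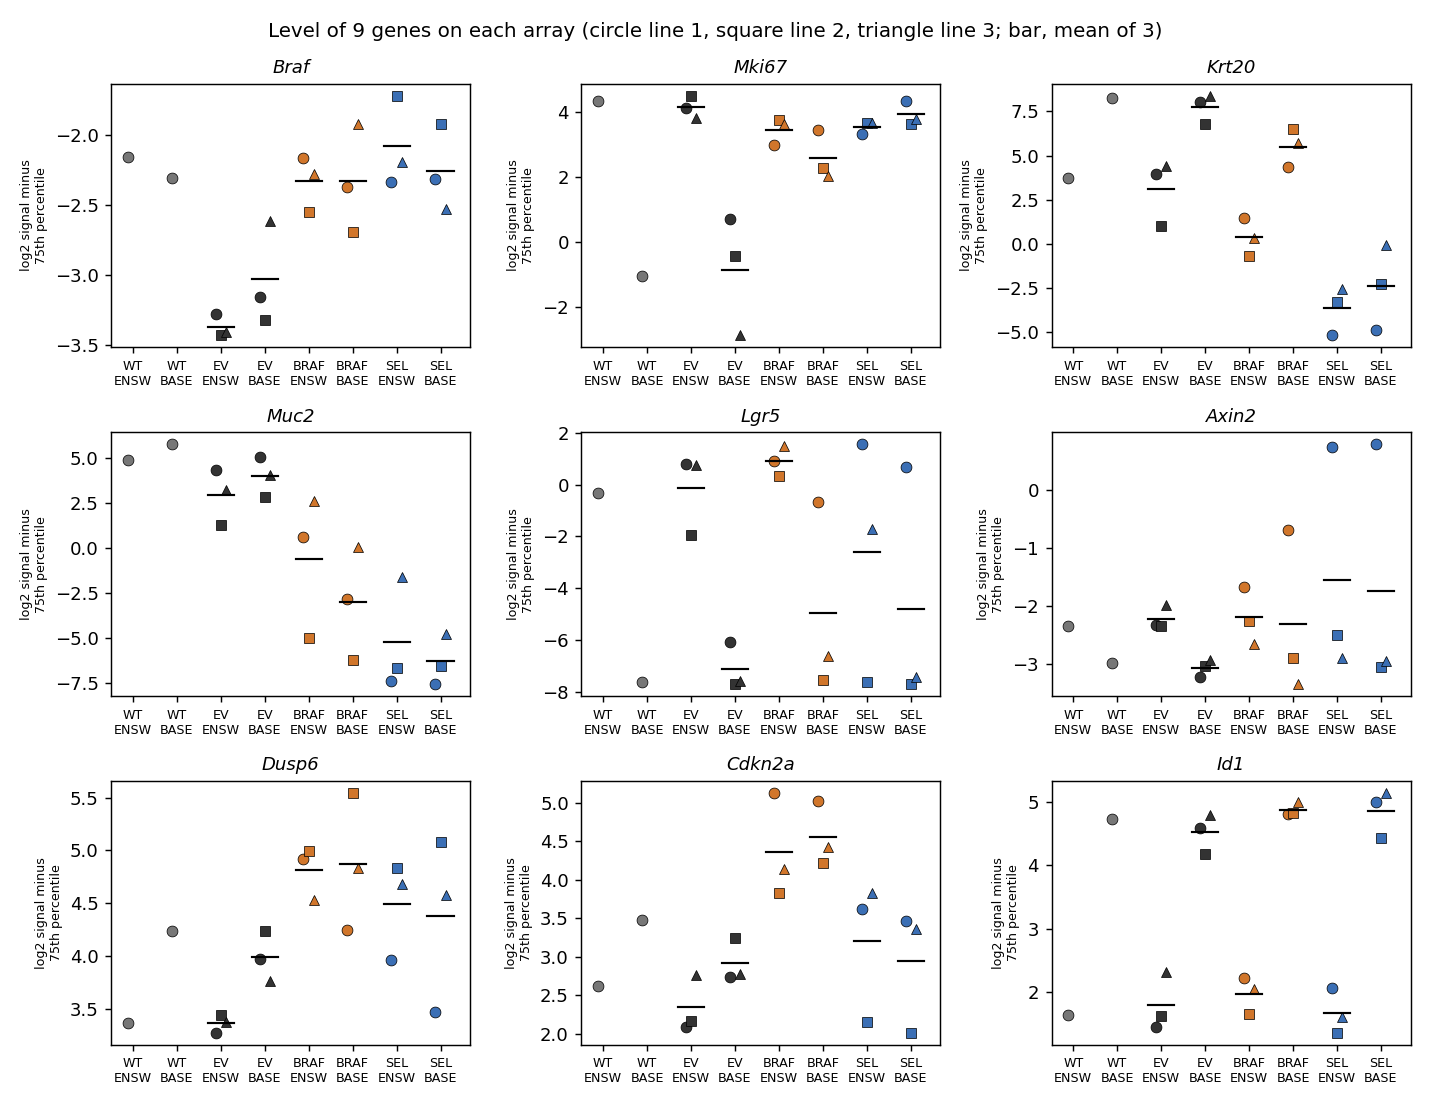
The level of 9 genes (log2 signal minus the array's 75th percentile) on each array, by organoid type and medium, with symbols for lines and bars for means of 3. Mki67 lies at -0.85 in EV organoids in base medium and at 3.94 in selected organoids in that medium, and Id1 lies at 4.52, 4.88 and 4.86 in EV, BRAF and selected organoids in base medium.

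Base medium was set against ENSW medium in EV organoids to see what control organoids do without niche factors. Cell-cycle genes fell. All 23 proliferation genes were lower, also when adjusted over the list alone, with a median of -4.56. Mki67, a marker of cycling cells, fell by 5.02 ± 0.65 (SE, n = 3 per group, adjusted p = 5.33e-05), and the replication helicase genes Mcm4 and Mcm6 fell by 3.69 ± 0.33 (adjusted p = 6.9e-06) and 4.56 ± 0.45 (adjusted p = 9.97e-06). Markers of differentiated colonocytes rose. Of 18 colonocyte genes 13 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 2.77. Krt20, a keratin of surface colonocytes, rose by 4.63 ± 1.17 (adjusted p = 0.0056), and the fatty acid binding protein gene Fabp2 rose by 5.36 ± 0.93 (adjusted p = 0.000428).

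Of 18 Wnt target genes 8 fell and 0 rose in EV organoids in base medium, with the same counts when adjusted over the list alone. Myc fell by 2.13 ± 0.36 (adjusted p = 0.000327), Cd44 by 2.01 ± 0.43 (adjusted p = 0.00179) and Ephb2 by 1.46 ± 0.23 (adjusted p = 0.000192). Among 12 stem cell genes 4 fell and 1 rose, the same adjusted over the list alone. Lgr5, a crypt stem cell marker, was at least 38.6-fold lower, since 0 of 3 base arrays were well above background, but this call was lost without any of 5 arrays (adjusted p up to 0.0881, without the base array of line 3) and with normexp (0.0565). Axin2 did not pass the test (-0.85 ± 1.03, adjusted p = 0.548). Of 8 BMP target genes 4 rose, also when adjusted over the list alone, among them Id1 by 2.73 ± 0.27 (adjusted p = 1.03e-05) and Id3 by 4.68 ± 0.86 (adjusted p = 0.000619). Chromatin genes changed in both directions, with 6 of 13 lower and 2 higher (6 and 2 adjusted over the list alone). Uhrf1 and Dnmt1, which maintain DNA methylation, fell by 5.95 ± 0.63 (adjusted p = 1.54e-05) and 1.85 ± 0.23 (adjusted p = 4.12e-05). The largest rises included the citrate transporter gene Slc13a2 (6.66 ± 0.98, adjusted p = 0.000118). Ssxb10 and Ssxb1 were at least 49.2-fold and 27.7-fold higher, with 0 of 3 ENSW arrays well above background (adjusted p = 3.29e-05 and 3.18e-05).

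In all, 9036 of 21424 genes were called between the media in EV organoids, 5017 higher and 4019 lower in base medium. Camera called proliferation lower (adjusted p = 1.31e-16, and 0.57 with an estimated correlation). In the same order, it called colonocyte genes higher (0.00161 and 0.57) and Wnt targets lower (0.01 and 0.74). BMP targets missed the threshold (adjusted p = 0.0629) and passed it with quantile normalization (0.0381), with the line as a block (0.0455) and without the ENSW array of line 1 or 3 or the base array of line 2 or 3 (0.0255 to 0.0458), while Cdx2 (0.64 ± 0.25, adjusted p = 0.0493) was lost with that block (0.0585), without a filter (0.069) and without any 1 of the 6 arrays (up to 0.151, without the ENSW array of line 3). Interferon genes (3 of 19 higher, 3 adjusted over the list alone, median 2.44) missed it (adjusted p = 0.0704) and passed it with quantile normalization (0.0474) and without the ENSW array of line 1 (0.00475) or the base array of line 3 (0.0176). Of the 73 named genes called here, 14 lost the call without 1 array. With slide as a random block 9908 genes were called and as a fixed block 10257. Within slides 1 and 2, list medians were -3.43 and -5.03 for proliferation, 2.11 and 2.96 for colonocyte genes, -1.47 and -2.23 for Wnt targets and 2.08 and 2.03 for BMP targets. For Cdkn1a, 2 of 3 probes went the way of the brightest one (2.47 ± 0.45).

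**Figure D3:**
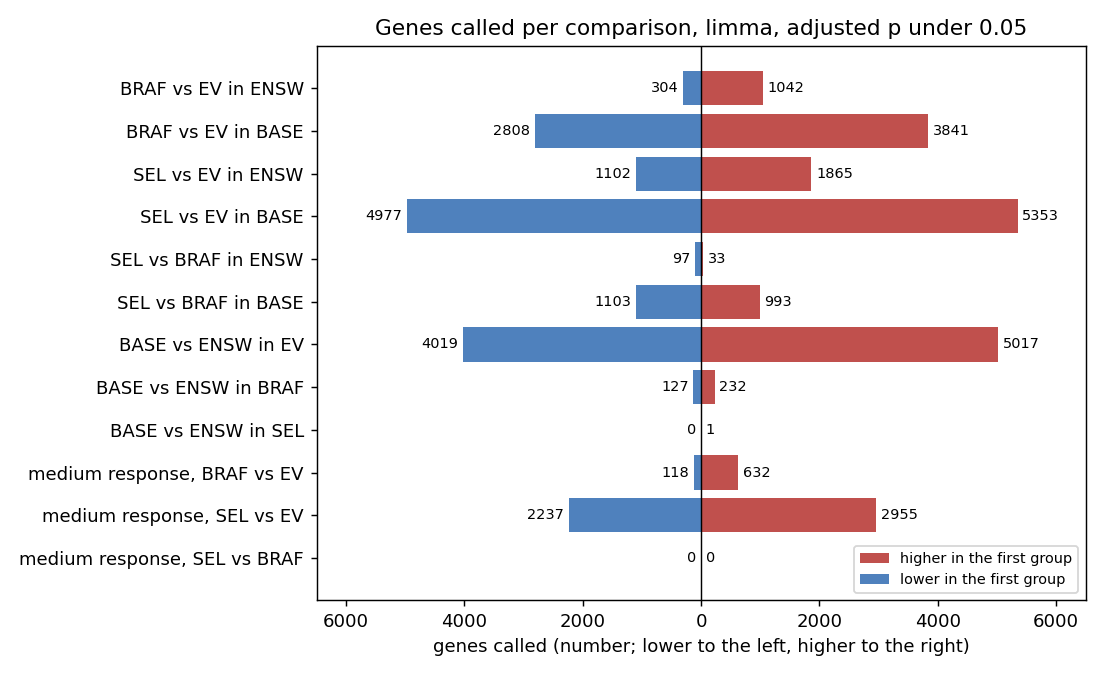
Bars give the number of genes called by limma, with media unpaired, per comparison. Genes higher in the first group lie right and lower ones left. Base against ENSW medium gave 5017 higher and 4019 lower genes in EV organoids, 232 and 127 in BRAF organoids and 1 and 0 in selected organoids.

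BRAF and EV organoids in ENSW medium were compared for the effect of the active allele in full culture medium. Colonocyte genes fell, with 8 of 18 lower and 0 higher (13 and 1 adjusted over the list alone) and a median of -3.03. Guca2a, a guanylin peptide of surface cells, fell by 4.40 ± 0.81 (SE, n = 3 per group, adjusted p = 0.00678) and Lypd8, a mucosal barrier protein, fell by 4.44 ± 0.71 (adjusted p = 0.00321). The chloride transporter gene Slc26a3 was at least 22.9-fold lower, with 0 of 3 BRAF arrays well above background (adjusted p = 0.00734, and 0.071 with normexp). Of 13 goblet cell genes 2 fell (2 adjusted over the list alone), with a median of -2.42 (-2.40 with bounds). Zg16, a mucus protein, fell by 6.38 ± 0.91 (adjusted p = 0.00178). Muc2 did not pass (-3.56 ± 1.97, adjusted p = 0.313), and neither did Krt20 (-2.76 ± 1.17, adjusted p = 0.175).

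Feedback genes of the MAPK pathway rose in BRAF organoids in ENSW medium, with 4 of 18 MAPK output genes higher (9 adjusted over the list alone), 0 lower and a median of 1.00 (0.98 with bounds). Spry1 rose by 1.70 ± 0.24 (adjusted p = 0.00147) and Spred1 by 0.99 ± 0.19 (adjusted p = 0.00778). Dusp6 (1.45 ± 0.38, adjusted p = 0.0383) and Etv4 (1.24 ± 0.32, adjusted p = 0.0353) lost the call without any 1 of the 6 arrays (up to 0.142 without BRAF line 2 and 0.117 without BRAF line 1) and without a filter (0.0539 and 0.0508), and Dusp6 also with slide as a random block (0.0599). Of 16 p53 and senescence genes 5 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.89. Eda2r, a p53 target, rose by 1.69 ± 0.20 (adjusted p = 0.000662) and Zmat3 by 1.24 ± 0.22 (adjusted p = 0.00623). Cdkn2a, the cell-cycle inhibitor gene, rose by 2.03 ± 0.48 (adjusted p = 0.0251), a call lost without any of 4 arrays (up to 0.105, without EV line 1). Proliferation genes did not move together (1 of 23 higher, 1 higher and 1 lower adjusted over the list alone, median -0.36, adjusted p = 0.0923), except without BRAF line 2 (0.00134). The hedgehog ligand gene Dhh was at least 14.0-fold higher, with 0 of 3 EV arrays well above background (adjusted p = 0.00701, and 0.0681 with normexp). The RNA-binding factor gene Celf2 rose by 3.55 ± 0.48 (adjusted p = 0.00147).

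There were 1346 genes called between BRAF and EV organoids in ENSW medium, 1042 higher and 304 lower. Camera called colonocyte (adjusted p = 1.87e-10), goblet (4.36e-05, adjusted p = 0.505 with an estimated correlation), enteroendocrine (median -1.65, -1.27 with bounds, 0.0024, adjusted p = 0.725 with an estimated correlation), MAPK output (1.78e-05) and p53 genes (2.22e-06, adjusted p = 0.127 with an estimated correlation). Colonocyte and MAPK output genes kept the call with an estimated correlation (0.0418 each). The enteroendocrine call, with 0 of 13 genes called (3 lower adjusted over the list alone), was lost without EV line 1 (0.0667) or BRAF line 2 (0.057). Fetal-like genes missed the threshold (adjusted p = 0.0797) and passed it with the line as a block (0.0331) or without EV line 2 (0.0446). Cholesterol synthesis (median -0.18, adjusted p = 0.0586) passed it with slide as a random block (0.0342) and without EV line 2 (0.0243) or BRAF line 2 (0.00523), and interferon genes (median -0.69, -0.21 with bounds, adjusted p = 0.101) passed it without EV line 2 or 3 (0.0294 without EV line 3) or BRAF line 2 (0.00113). With the line as a block Csf1r and Crip2 missed it (0.0507 each), as they did without a filter (0.068 and 0.0585) and Crip2 with slide as a random block (0.0554). The count dropped to 372 without EV line 1, 483 without EV line 3, 392 without BRAF line 2 and 851 without BRAF line 3, and 18 of 38 named genes lost the call without 1 array. EV and BRAF arrays shared no slide, so slide and organoid type cannot be told apart here. With slide as a random block, which does not part them, 1205 genes were called.

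In base medium the same comparison asked whether BRAF organoids differ from EV organoids once niche factors are gone. Proliferation genes were higher in BRAF organoids, with 21 of 23 higher (21 adjusted over the list alone), 0 lower and a median of 3.33. Mki67 was higher by 3.45 ± 0.65 (SE, n = 3 per group, adjusted p = 0.00143) and Cdk1, the mitotic kinase gene, by 4.49 ± 0.58 (adjusted p = 0.000149). Colonocyte genes were lower, with 12 of 18 called lower (13 adjusted over the list alone) and a median of -3.17, among them Slc26a3 (-6.25 ± 1.05, adjusted p = 0.000667) and Fabp2 (-5.59 ± 0.93, adjusted p = 0.000668). Of 13 goblet genes 5 fell, also when adjusted over the list alone. Zg16 fell by 7.27 ± 0.91 (adjusted p = 0.000123) and Tff3, a mucus-associated peptide, by 5.77 ± 1.23 (adjusted p = 0.00326). Muc2 fell by 6.997 ± 1.97 (adjusted p = 0.016), a call lost without either of 2 arrays (up to 0.0715, without BRAF line 2).

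Of 13 enteroendocrine genes 6 fell in BRAF organoids in base medium (7 adjusted over the list alone), with Pyy, a gut peptide hormone, lower by 3.94 ± 0.90 (adjusted p = 0.00486). Wnt targets Myc and Cd44 were higher by 1.87 ± 0.36 (adjusted p = 0.00163) and 2.15 ± 0.43 (adjusted p = 0.00206). In all 6 of 18 were higher, also when adjusted over the list alone. MAPK output genes rose in 6 of 18 cases (7 adjusted over the list alone), among them Etv4 (1.67 ± 0.32, adjusted p = 0.0016) and Ccnd1 (2.53 ± 0.48, adjusted p = 0.00141). Of 16 p53 genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), among them Eda2r (2.75 ± 0.20, adjusted p = 3.02e-06) and Phlda3 (2.47 ± 0.27, adjusted p = 6.05e-05). Of 19 cholesterol synthesis genes 7 rose (8 adjusted over the list alone), among them Idi1 (1.27 ± 0.26, adjusted p = 0.0024). The homeobox gene Rhox5 had the largest rise among the named genes (9.05 ± 1.85, adjusted p = 0.00252). Zscan4e and Zscan4f were at least 30.3-fold and 30.0-fold higher, with 0 of 3 EV arrays well above background (adjusted p = 0.0139 and 0.0167), and both calls were lost without EV line 3 (0.0529 and 0.0635) and with normexp (0.0976 and 0.0801).

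There were 6649 genes called between BRAF and EV organoids in base medium, 3841 higher and 2808 lower, and 4368 without EV line 3. Camera called proliferation (adjusted p = 7.68e-12, and 0.445 with an estimated correlation) and, in the same order, cholesterol synthesis (0.0127 and 0.84) higher. It called colonocyte (4.67e-06 and 0.445), goblet (0.00123 and 0.675) and enteroendocrine genes (0.00123 and 0.704) lower. The p53 (0.0151 and 0.675) and MAPK output lists (0.0265 and 0.445) were also called higher. Cholesterol, p53 and MAPK output were lost without EV line 2 (0.0682 each), MAPK output also without BRAF line 3 (0.0742, and 0.0654 without both of its arrays). Wnt targets missed the threshold (adjusted p = 0.0652) and passed it with the line as a block (0.0366) or without EV line 1 (0.0373) or BRAF line 2 (0.0237). Interferon genes (median -1.52, adjusted p = 0.0647) passed it with slide as a random block (0.0298) and without EV line 3 (0.00807) or BRAF line 2 (0.00758). Dusp6 (0.88 ± 0.38, adjusted p = 0.0943) passed it with the line as a block (0.0328). Of 64 named genes 16 lost the call without 1 array, 1 of 3 Itgam probes went the way of the brightest, and 6210 genes were called with slide as a random block.

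Base and ENSW medium were compared in BRAF organoids, and the size of that response was set against the response of EV organoids. Colonocyte genes rose, with 6 of 18 higher (12 adjusted over the list alone), 0 lower and a median of 2.28 (2.03 with bounds). The acute phase gene Saa2 rose by 4.49 ± 0.60 (SE, n = 3 per group, adjusted p = 0.00681), and Id1, a BMP target, by 2.91 ± 0.27 (adjusted p = 0.000738). These were the 2 of 23 named genes that kept the call without any 1 array. Krt20 (5.15 ± 1.17, adjusted p = 0.0438), Guca2a (4.97 ± 0.81, adjusted p = 0.0125) and Id3 (4.35 ± 0.86, adjusted p = 0.0259) rose, but lost the call without 1 array (up to 0.201, 0.0746 and 0.127, each without an array of BRAF line 2), and Krt20 also without a filter (0.0608). Of 8 BMP targets 3 rose (4 adjusted over the list alone), with a median of 1.44. Of 23 proliferation genes 0 were called with limma (3 lower adjusted over the list alone), with a median of -0.87, and Mki67 did not pass (-0.87 ± 0.65, adjusted p = 0.503). Lgr5 did not pass either (-5.87 ± 2.42, adjusted p = 0.218), with 1 of 3 base arrays and 3 of 3 ENSW arrays well above background, but passed with the culture as a random block (adjusted p = 0.0241).

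There were 359 genes called between the media in BRAF organoids, 232 higher and 127 lower. With normexp 290 were higher and 369 lower and with the authors' values 256 and 310, so the direction of the majority depended on the processing. With the culture as a random block, which takes both media of a culture as a pair, 4078 genes were called (2146 higher, 1932 lower, 359 shared). With the line as a block 616 were called, 350 of them shared, with slide as a random block 725 and as a fixed block 523. The count went to 184, 16 and 135 without the ENSW array of lines 1, 2 and 3, to 1722, 17 and 36 without the base array of lines 1, 2 and 3, and to 22 without both arrays of BRAF line 3. Camera called colonocyte (adjusted p = 8.07e-09, adjusted p = 0.143 with an estimated correlation), cholesterol synthesis (median 0.62, 1.26e-05, adjusted p = 0.529 with an estimated correlation), BMP target (0.000547, adjusted p = 0.21 with an estimated correlation) and interferon genes (median 1.54, 1.40 with bounds, 0.00393, adjusted p = 0.759 with an estimated correlation) higher. It called proliferation (7.59e-08, adjusted p = 0.539 with an estimated correlation), MAPK output (median -0.53, -0.46 with bounds, 0.00186, adjusted p = 0.149 with an estimated correlation) and Wnt target genes (median -0.79, -0.68 with bounds, 0.00666, adjusted p = 0.697 with an estimated correlation) lower. Within slides 4, 5 and 6 the medians were 1.73, 2.44 and 2.81 for colonocyte genes, 1.15, 0.72 and 1.42 for BMP targets, 0.75, 0.48 and 0.42 for cholesterol synthesis and 0.51, 1.39 and 2.49 for interferon genes, -0.030, -1.47 and -1.49 for proliferation, -0.62, -0.58 and -0.16 for MAPK output and -0.28, -0.89 and -0.94 for Wnt targets. Of 19 interferon genes 0 were called (1 higher adjusted over the list alone), and that list lost its call without the ENSW array of line 1 (0.112), the base array of line 2 (0.2) or both arrays of line 3 (0.0913). Wnt targets lost theirs without the base array of line 2 (0.0958).

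The response to base medium differed between BRAF and EV organoids for 750 genes, 632 with a higher and 118 with a lower change in BRAF organoids. Proliferation genes made up the clearest group, with 19 of 23 called (20 adjusted over the list alone) and a median difference in response of 3.42 (adjusted p = 3.99e-21, adjusted p = 0.381 with an estimated correlation). The cytokinesis gene Racgap1 differed by 3.27 ± 0.41 (adjusted p = 0.00415). Mki67 differed by 4.15 ± 0.92 (adjusted p = 0.0341), a call lost without any of 6 arrays (up to 0.0989, without the base array of BRAF line 1). Kif27 and Kynu were called with a lower response (adjusted p = 0.00479 and 0.00493). They were well above background on 3 of 3 EV base arrays and on 0 of 3 arrays of each other group, so the size of their difference was not resolved, and Kynu missed the threshold with normexp (0.111). Cholesterol synthesis genes were also called (2 of 19 higher, 5 adjusted over the list alone, median 0.65, adjusted p = 8.99e-06, adjusted p = 0.631 with an estimated correlation). With the culture as a random block 4239 genes were called (2554 higher, 1685 lower, 750 shared), with the line as a block 1377, 749 of them shared, with slide as a random block 1371 and as a fixed block 176. The count was 177, 51 and 63 without the EV ENSW arrays of lines 1, 2 and 3, 1903 and 275 without the EV base arrays of lines 2 and 3, 71, 463 and 82 without the BRAF ENSW arrays of lines 1, 2 and 3, and 59, 389 and 1430 without the BRAF base arrays of lines 1, 2 and 3. It was 179 without both arrays of BRAF line 3.

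Selected organoids were compared with EV organoids in ENSW medium, where both had niche factors. Genes of differentiated cells fell. Of 18 colonocyte genes 13 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -4.58 (-4.49 with bounds). Guca2a fell by 8.57 ± 0.81 (SE, n = 3 per group, adjusted p = 3.16e-05), Krt20 by 6.79 ± 1.17 (adjusted p = 0.00256, 2 of 3 selected arrays well above background) and Car1, a carbonic anhydrase of colonocytes, by 8.05 ± 0.91 (adjusted p = 0.000124). The colonic homeobox genes Cdx1 and Cdx2 fell by 10.10 ± 1.91 (adjusted p = 0.00447, 2 of 3 selected arrays well above background) and 1.14 ± 0.25 (adjusted p = 0.00936). Of 13 goblet genes 8 fell (11 adjusted over the list alone), with a median of -5.32. Tff3 was at least 768-fold lower, with 0 of 3 selected arrays well above background (adjusted p = 0.000102). Muc2 fell by 8.19 ± 1.97 (adjusted p = 0.0161, 1 of 3 selected arrays well above background), a call lost without any of 4 arrays (up to 0.0697, without EV line 1).

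Of 13 enteroendocrine genes 6 fell in selected organoids in ENSW medium (9 adjusted over the list alone), and Chgb, a granin of endocrine granules, was at least 256-fold lower (adjusted p = 0.00416, 0 of 3 selected arrays well above background). Of 19 cholesterol synthesis genes 13 fell (15 adjusted over the list alone), with a median of -0.85. Hmgcs1, an early enzyme of the pathway, fell by 1.44 ± 0.24 (adjusted p = 0.00215). MAPK output genes rose in 5 of 18 cases (10 adjusted over the list alone), with a median of 1.07 (0.81 with bounds), among them Spry1 (1.98 ± 0.24, adjusted p = 0.000196) and Etv4 (1.73 ± 0.32, adjusted p = 0.00401). Of 16 p53 genes 8 rose (9 adjusted over the list alone), among them Eda2r (2.07 ± 0.20, adjusted p = 4.75e-05). Cdkn2a did not pass (0.86 ± 0.48, adjusted p = 0.243). The largest named rise was that of the microtubule gene Eml1 (8.74 ± 1.05, adjusted p = 0.000218), and Tesc rose by 6.36 ± 0.95 (adjusted p = 0.000996). Mki67 (-0.60 ± 0.65, adjusted p = 0.572) and Lgr5 (-2.46 ± 2.42, adjusted p = 0.534) did not pass.

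There were 2967 genes called between selected and EV organoids in ENSW medium, 1865 higher and 1102 lower. Camera called colonocyte genes lower (adjusted p = 7.56e-16, kept at 0.0187 with an estimated correlation). In the same order, it called cholesterol synthesis (5.91e-11 and 0.133), goblet (8.76e-11 and 0.128) and enteroendocrine genes (4.38e-06 and 0.349) lower. It called p53 (5.06e-05 and 0.166) and MAPK output genes (0.000563 and 0.1) higher. Dusp6 missed the threshold (1.13 ± 0.38, adjusted p = 0.063) and passed it with the line as a block (0.0203) or quantile normalization (0.0449), and fetal-like genes (adjusted p = 0.55) passed it without both arrays of selected line 1 (0.0399). Interferon genes (0 of 19 called, median -0.86, adjusted p = 0.102) passed it without EV line 2 (0.00972) or 3 (0.0247) or selected line 2. The count was 1131 without EV line 1, 1236 without EV line 3, and 1820, 1518 and 1826 without selected lines 1, 2 and 3, and 11 of 50 named genes lost the call without 1 array. These groups shared no slide, and 2308 genes were called with slide as a random block.

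In base medium, the medium of their selection, selected organoids were again compared with EV organoids. All 23 proliferation genes were higher, also when adjusted over the list alone, with a median of 4.52. Mki67 was higher by 4.79 ± 0.65 (SE, n = 3 per group, adjusted p = 3.81e-05), Mcm4 by 3.84 ± 0.33 (adjusted p = 1.55e-06), and Ckap2, a mitotic spindle gene, at least 50.7-fold, with 0 of 3 EV arrays well above background (adjusted p = 1.25e-07). Of 18 colonocyte genes 17 were lower, also when adjusted over the list alone, with a median of -8.64 (-8.44 with bounds). Guca2a fell by 12.63 ± 0.81 (adjusted p = 1.53e-07), Krt20 fell by 10.16 ± 1.17 (adjusted p = 1.03e-05) and Lypd8 fell by 10.86 ± 0.71 (adjusted p = 1.76e-07). Of 13 goblet genes 7 fell (7 adjusted over the list alone). Tff3 was at least 3590-fold lower (adjusted p = 1.82e-06, 0 of 3 selected arrays well above background) and Muc2 fell by 10.30 ± 1.97 (adjusted p = 0.000632, 1 of 3 selected arrays well above background). Of 13 enteroendocrine genes 11 fell (11 adjusted over the list alone), among them Sct, the secretin gene (-6.98 ± 1.13, adjusted p = 0.000166).

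Interferon response genes fell in selected organoids in base medium, with 12 of 19 lower (13 adjusted over the list alone), 0 higher and a median of -3.25. The sensor gene Ifih1 fell by 3.25 ± 0.55 (adjusted p = 0.000245). Of 18 Wnt targets 7 rose (6 adjusted over the list alone), with a median of 1.97 (1.75 with bounds). Sox9, a progenitor transcription factor gene, rose by 4.67 ± 0.84 (adjusted p = 0.000389), Cd44 by 3.95 ± 0.43 (adjusted p = 6.71e-06) and Myc by 1.91 ± 0.36 (adjusted p = 0.000535). Of 13 chromatin genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with Uhrf1 higher by 5.64 ± 0.63 (adjusted p = 7.98e-06) and Ezh2, a histone methyltransferase gene, by 1.37 ± 0.20 (adjusted p = 7.97e-05). MAPK output genes rose in 8 of 18 cases and fell in 1 (8 and 1 adjusted over the list alone), with Etv4 higher by 3.66 ± 0.32 (adjusted p = 1.57e-06), while Dusp6 did not pass (0.38 ± 0.38, adjusted p = 0.432). Cdkn2a did not pass (0.027 ± 0.48, adjusted p = 0.969), with 1 of its 2 probes going the other way.

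There were 10330 genes called between selected and EV organoids in base medium, 5353 higher and 4977 lower. Camera called proliferation higher (adjusted p = 2.05e-12, and 0.408 with an estimated correlation). In the same order, it called colonocyte (3.78e-10 and 0.102), goblet (0.000662 and 0.584), enteroendocrine (0.00131 and 0.724) and interferon genes lower (0.00235 and 0.78). MAPK output (0.0267, adjusted p = 0.408 with an estimated correlation), Wnt targets (0.0267, adjusted p = 0.78 with an estimated correlation) and chromatin genes (0.0485, adjusted p = 0.584 with an estimated correlation) were called higher by narrow margins. The chromatin call was lost with the line as a block (0.086), with slide as a random block (0.0552), and without EV line 2 or selected line 1 or 2 (0.107 without selected line 1). The Wnt call was lost with slide as a random block (0.0552) and without EV line 2 or 3 or selected line 1 (0.24 without selected line 1), and the MAPK call without selected line 2 (0.057). Without both arrays of selected line 1 the Wnt median was 0.24. For Itgam, 1 of 3 probes went the way of the brightest (-1.39 ± 0.21). With slide as a random block 9695 genes were called, and 11 of 73 named genes lost the call without 1 array.

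Base and ENSW medium were compared in selected organoids. Id1 rose by 3.19 ± 0.27 (SE, n = 3 per group, adjusted p = 0.000229), from 1.67 ± 0.36 to 4.86 ± 0.38 (SD), and was the 1 gene called by limma, while 319 genes had an unadjusted p under 0.05. Id1 kept the call without any 1 array and under both blocks, but lost it with only the arrays compared. BMP target genes moved upward as a list (1 of 8 called, 5 adjusted over the list alone, median 1.30, adjusted p = 1.65e-15), and so did cholesterol synthesis genes (0 of 19 called, 6 adjusted over the list alone, median 0.59, adjusted p = 1.1e-20). Both lists kept their call with an estimated correlation (0.00452 and 0.0407). Proliferation genes had 0 of 23 members called (0 adjusted over the list alone) and a median of 0.32 (adjusted p = 0.004, adjusted p = 0.728 with an estimated correlation), and Mki67 differed by 0.37 ± 0.65 (adjusted p = 1). Krt20 differed by 1.25 ± 1.17 (adjusted p = 1).

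MAPK output (median -0.25, adjusted p = 0.0107, adjusted p = 0.189 with an estimated correlation), Wnt target (median -0.22, adjusted p = 0.0391, adjusted p = 0.728 with an estimated correlation) and stem cell genes (median -0.35, adjusted p = 0.0391, adjusted p = 0.281 with an estimated correlation) were called lower in base medium in selected organoids, with 0 members called. The stem cell call was lost without the ENSW array of line 1 (0.203) or 3 or the base array of line 2 (0.376), and the MAPK call without the base array of line 1 (0.258) or the ENSW array of line 2 or 3 (0.109). The Wnt call was lost without the base array of line 2 (0.649) or 3 (0.782), and its direction turned without the ENSW array of line 1 (0.38). The proliferation call was lost without the base array of line 1 (0.258) and without both arrays of that line (0.319), and with slide as a random block the Wnt target and stem cell calls were lost (0.0509 each). Within slides 3 and 4 the medians were 0.55 and 0.70 for cholesterol synthesis, 1.02 and 1.88 for BMP targets, 0.31 and 0.24 for proliferation, -0.27 and -0.37 for MAPK output, -0.31 and -0.40 for Wnt targets and -0.37 and -0.67 for stem cell genes. Colonocyte genes (median 0.14, adjusted p = 0.114) were called without selected line 1 (0.049). With the line or the slide as a block 1 gene was called, and with the culture as a random block 3.

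The response to base medium differed between selected and EV organoids for 5192 genes, 2955 with a higher and 2237 with a lower change in selected organoids. With the culture as a random block 9246 genes were called, 4121 higher and 5125 lower (5192 shared), so the direction of the majority depended on the fit. Proliferation genes again formed the clearest group, with 21 of 23 called (23 adjusted over the list alone) and a median difference of 4.91 (adjusted p = 4.27e-19, adjusted p = 0.49 with an estimated correlation). Mki67 differed by 5.39 ± 0.92 (adjusted p = 0.00129) and Racgap1 by 4.51 ± 0.41 (adjusted p = 0.000113). Colonocyte genes were called with a median of -2.42 (-2.36 with bounds, adjusted p = 0.0107, adjusted p = 0.645 with an estimated correlation), with 3 of 18 lower, also when adjusted over the list alone, among them Guca2a (-4.06, adjusted p = 0.0191). Cholesterol synthesis was called with a median of 0.68 (adjusted p = 0.00161, adjusted p = 0.765 with an estimated correlation) and 5 of 19 genes (5 adjusted over the list alone). Hells and Uhrf1, both chromatin genes, differed by 4.74 (adjusted p = 0.000205) and 6.13 (adjusted p = 0.000566), with 1 and 2 of 3 EV base arrays well above background. All 9 named genes kept the call without any 1 array. Wnt targets missed the threshold (adjusted p = 0.057) and passed it with the line as a block (0.0242), with slide as a random block (0.0485), without both arrays of selected line 1 (0.0239), and without the EV base array of line 1, the selected ENSW array of line 1 or the selected base array of line 2 or 3 (0.0052 to 0.0372). Interferon genes (median -2.60, adjusted p = 0.057) passed it with quantile normalization (0.0468), with slide as a random block (0.0469), and without the EV ENSW array of line 1, the EV base array of line 3, the selected ENSW array of line 1 or the selected base array of line 2 (0.00281 to 0.0294). With slide as a random block 6095 and as a fixed block 6307 genes were called. The median over all genes was -0.19 in this contrast (-0.074 after quantile normalization).

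Selected and BRAF organoids had 0 genes called by limma for a differing response to base medium, with 1798 at an unadjusted p under 0.05. With the culture as a random block, which pairs the media, 335 genes were called (136 higher, 199 lower), 0 with the line as a block and 1 with slide as a fixed block. Leaving out the ENSW array of selected line 1 or of BRAF line 3 gave 1 call each. As lists, proliferation had a median difference of 1.35 (adjusted p = 4.87e-11, adjusted p = 0.724 with an estimated correlation) and colonocyte genes one of -2.11 (-1.87 with bounds, adjusted p = 3.81e-07, adjusted p = 0.296 with an estimated correlation), with 0 and 5 members called adjusted over the list alone. Interferon genes had a median of -1.70 (-1.69 with bounds, adjusted p = 0.00376, adjusted p = 0.896 with an estimated correlation) and 0 members called. That call was lost without the base array of selected line 1, the ENSW array of selected line 2 (0.064), the ENSW array of BRAF line 1, the base array of BRAF line 2 (0.27) or both arrays of BRAF line 3 (0.091).

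**Figure D4:**
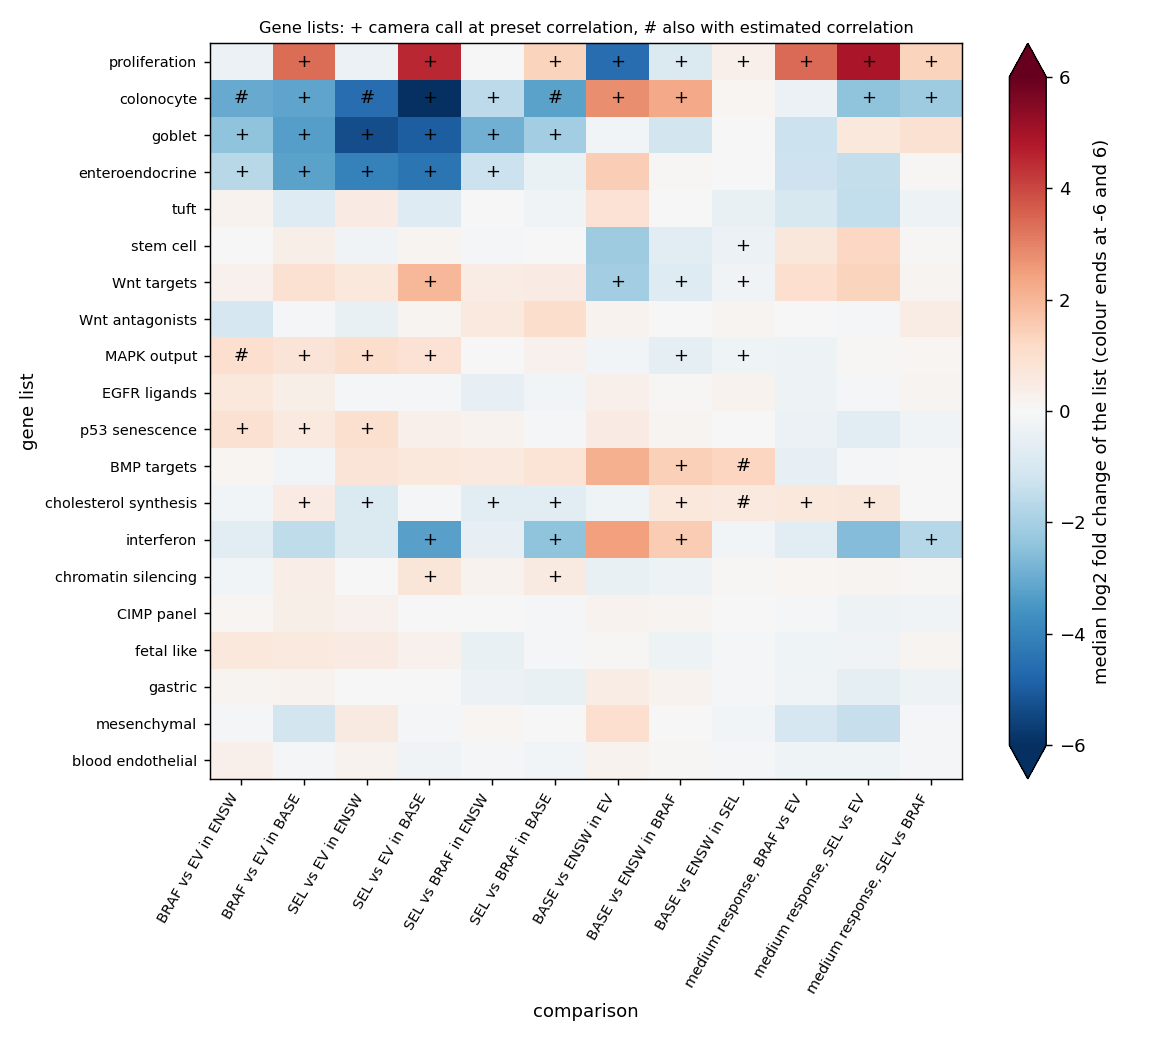
Colour gives the median log2 difference of each gene list in each comparison (scale ends at -6 and 6), a plus marks a camera call at the preset correlation and a hash a call that also holds with an estimated correlation. Proliferation has medians of -4.56 for the medium in EV organoids, 3.33 for BRAF and 4.52 for selected against EV organoids in base medium.

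Selected organoids were compared with BRAF organoids to find what selection added to the active allele. In ENSW medium Hsd17b2, a steroid dehydrogenase gene, was at least 75.4-fold lower (adjusted p = 4.26e-08) and Tff3 at least 145-fold lower (adjusted p = 0.00325, and 0.094 with normexp), with 0 of 3 selected arrays well above background for each. Tstd1 fell by 6.39 ± 0.43 (SE, n = 3 per group, adjusted p = 6.67e-06). Colonocyte genes had 4 of 18 members lower (6 adjusted over the list alone) and a median of -1.58. Car1, Guca2a, Guca2b and Lypd8, the 4 called ones, each lost the call without any of 5 arrays (adjusted p up to 0.163, without selected line 3), and with the culture as a random block Car1 (0.0821), Guca2a (0.0671) and Guca2b (0.0873) also missed the threshold. With normexp all 4 missed it (Car1 0.0561, Guca2a 0.162, Guca2b 0.616, Lypd8 0.143), as did Guca2a (0.0723) and Guca2b (0.308) with the authors' values and Car1 without a filter (0.055). Cholesterol synthesis genes had 1 of 19 members called lower and 13 adjusted over the list alone, with a median of -0.68. The choline phosphate enzyme gene Pcyt1b rose by 2.47 ± 0.36 (adjusted p = 0.00531). Mki67 (0.099 ± 0.65, adjusted p = 0.985) and Cdkn2a (-1.16 ± 0.48, adjusted p = 0.395) did not pass.

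There were 130 genes called between selected and BRAF organoids in ENSW medium, 33 higher and 97 lower. With the line as a block 234 were called (80 higher, 154 lower, 127 shared), with slide as a random block 136, with slide as a fixed block 414 (66 shared) and without both arrays of selected line 1 236 (88 shared). The count was 85, 65 and 44 without selected lines 1, 2 and 3, and 50 and 80 without BRAF lines 1 and 2, and 14 of 21 named genes lost the call without 1 array. Camera called cholesterol synthesis (adjusted p = 1.89e-13, adjusted p = 0.148 with an estimated correlation), colonocyte (4.92e-09, adjusted p = 0.148 with an estimated correlation), goblet (median -2.89, -2.77 with bounds, 5.98e-08, adjusted p = 0.27 with an estimated correlation) and enteroendocrine genes lower (median -1.31, -0.44 with bounds, 0.00441, adjusted p = 0.861 with an estimated correlation). The enteroendocrine call was lost without BRAF line 1 (0.071) or 3 (0.0563, and 0.0554 without both of its arrays). Within slide 4, which held selected line 3 and BRAF line 1, list medians were -1.69 for colonocyte, -2.67 for goblet, -2.13 for enteroendocrine and -0.54 for cholesterol synthesis genes.

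In base medium selected organoids had lower colonocyte genes than BRAF organoids, with 13 of 18 lower (14 adjusted over the list alone), 0 higher and a median of -3.23 (-3.09 with bounds). Krt20 fell by 7.92 ± 1.17 (SE, n = 3 per group, adjusted p = 0.00114), Guca2a fell by 8.99 ± 0.81 (adjusted p = 1.85e-05), Cdx2 fell by 1.18 ± 0.25 (adjusted p = 0.00942) and Hsd17b2 was at least 339-fold lower (adjusted p = 4.11e-10, 0 of 3 selected arrays well above background). Proliferation genes were higher, with 7 of 23 called (13 adjusted over the list alone) and a median of 1.35. Mcm4 rose by 1.75 ± 0.33 (adjusted p = 0.00576) and the cyclin gene Ccne1 by 1.81 ± 0.34 (adjusted p = 0.00555), while Mki67 did not pass (1.34 ± 0.65, adjusted p = 0.216). Without both arrays of selected line 1, 2 proliferation genes were called. Cholesterol synthesis had 7 of 19 genes lower (13 lower and 1 higher adjusted over the list alone). Cdkn2b, a cell-cycle inhibitor gene, fell by 2.27 ± 0.43 (adjusted p = 0.00553). Cdkn2a fell by 1.61 ± 0.48 (adjusted p = 0.0484), a call lost without any 1 of the 6 arrays (up to 0.161, without selected line 2), and with quantile normalization (0.0571), normexp (0.0702), the authors' values (0.0663) and no filter (0.0686). Etv4 rose by 1.99 ± 0.32 (adjusted p = 0.00214) and Tesc by 5.45 ± 0.95 (adjusted p = 0.00352).

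There were 2096 genes called between selected and BRAF organoids in base medium, 993 higher and 1103 lower. With slide as a random block 2033 were called, with slide as a fixed block 1329 (700 shared) and without both arrays of BRAF line 3 964. The count was 1251 and 1254 without selected lines 1 and 3, and 3372, 840 and 1055 without BRAF lines 1, 2 and 3, and 19 of 47 named genes lost the call without 1 array. Camera called colonocyte (adjusted p = 6.33e-13, kept at 0.0402 with an estimated correlation), cholesterol synthesis (median -0.68, 4.84e-07, adjusted p = 0.477 with an estimated correlation), interferon (median -2.41, 0 of 19 called, 0.00276, adjusted p = 0.611 with an estimated correlation) and goblet genes lower (median -2.07, -1.62 with bounds, 0.00287, adjusted p = 0.611 with an estimated correlation). It called proliferation (4.36e-09, adjusted p = 0.496 with an estimated correlation) and chromatin genes higher (median 0.53, 4 of 13 higher, 6 adjusted over the list alone, 0.00276, adjusted p = 0.363 with an estimated correlation). Enteroendocrine genes missed the threshold (adjusted p = 0.132) and passed it with the line as a block (0.0442) or without BRAF line 2 (0.0474), and interferon genes missed it without both arrays of selected line 1 (0.0659). Within slide 4, list medians were -3.07 for colonocyte, -1.71 for goblet, -0.75 for cholesterol synthesis, 0.89 for proliferation, 0.0040 for chromatin and -0.054 for interferon genes.

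The other lists were not called by camera in any of the 12 contrasts. For selected against EV organoids in base medium the medians were -0.78 for tuft (adjusted p = 0.653), 0.26 for fetal-like (0.858), 0.19 for Wnt antagonist (-0.0054 with bounds, 0.918), -0.12 for EGFR ligand (0.0060 with the authors' values, 0.949), 0.027 for CIMP (0.949), -0.20 for blood and endothelial (0.633), -0.082 for mesenchymal (0.546) and 0.0069 for gastric genes (0.546). The mean of the gastric list was -0.50, so its mean and test lay below 0 and its median above. The mesenchymal list in BRAF against EV organoids in ENSW medium had a median of -0.059 and a mean of -0.20, while its test pointed up (adjusted p = 0.545), and in selected against BRAF organoids in ENSW medium its median was 0.14 and its test pointed down (adjusted p = 0.766). Tuft genes in selected against BRAF organoids in base medium had a median of -0.22 and a test that pointed up (adjusted p = 0.861), but the median was 0.0089 with bounds and 0.049 with the authors' values. With the authors' values, goblet medians were -2.95 for selected against EV organoids in base medium and -1.66 and -0.80 for selected against BRAF organoids in ENSW and base medium. Enteroendocrine medians were -0.96 and -1.98 (BRAF against EV, ENSW and base medium), -1.86 and -2.29 (selected against EV) and -0.37 (selected against BRAF, ENSW). Other medians of called lists that moved by over 1.5 times with those values were -1.13 for Wnt targets for the medium in EV and -0.11 in selected organoids, 0.83 for BMP targets in BRAF and -0.16 for MAPK output in selected organoids, 0.48 for MAPK output in BRAF against EV and -1.56 for interferon genes in selected against BRAF organoids in base medium, and -1.36 for the colonocyte response of selected against BRAF organoids. Of all lists and contrasts, the calls that held with an estimated correlation were colonocyte and MAPK output genes for BRAF against EV organoids in ENSW medium, colonocyte genes for selected against EV organoids in ENSW medium and against BRAF organoids in base medium, and cholesterol synthesis and BMP targets for the medium in selected organoids. Single members of the uncalled lists did change. Alox5ap, a tuft cell gene, rose in selected against EV organoids in ENSW medium by 4.73 ± 0.79 (SE, n = 3 per group, adjusted p = 0.00223) and Thy1, a mesenchymal marker, was at least 174-fold lower in base medium (adjusted p = 6.18e-07, 0 of 3 selected arrays well above background).

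Of the 4 Y-linked genes, 3 separated the arrays by a wide margin. On the ENSW and base arrays of BRAF line 3, Ddx3y lay at -7.94 and -7.84, Uty at -7.69 and -7.60 and Eif2s3y at -6.12 and -5.65. On the other 16 arrays of the 6 groups Ddx3y lay between -2.45 and -1.23, Uty between -4.61 and -2.73 and Eif2s3y between 0.39 and 1.77. Kdm5d was dim on all of them (-8.02 and -7.97 against -7.82 to -4.98). Xist was well above background on 0 of 20 arrays with its 2 probes.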

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

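The tests of spread and of exchanged media for the response to base medium, and all tests for the Y-linked and the Zscan4 patterns, were chosen only after the result was seen, while the test of genes at background and the splits of the arrays were chosen earlier. Values are listed here because organoid types differed in their response to the medium by a test of that difference, or because a wild-type array, outside the comparisons, lay above every EV array of its medium.

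The response to base medium differed from EV organoids for 750 genes in BRAF and 5192 in selected organoids. Over the 9036 genes called in EV organoids, each EV line's slope on the mean change of the other 2 was 0.815, 0.84 and 1.31. The slope on the mean EV change was 0.155, 0.53 and 0.478 for BRAF and -0.0453, 0.0338 and 0.0218 for selected lines. This argued against a larger spread around a response of the same size. Id1, the 1 gene called in selected organoids, rose by at least 2.94 in each line. This argued against an unchanged or exchanged medium, but 1 BMP target cannot show each factor gone. Over the 7735 of the 9036 genes well above background on all 18 arrays the highest selected slope was 0.0487. This argued against genes that could fall no further. No biological explanation was tested. EV slides held no other organoid type, but each response was taken within a slide.

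The Y-linked genes Ddx3y, Uty and Eif2s3y lay at -7.94 to -5.65 on both arrays of BRAF line 3, each below its level on all other arrays. Loss of signal was argued against, since 64.7% and 65.2% of these arrays' spots lay well above background, against 59.6% to 64% on the other 18. RNA from a female was not decided, as no female array showed the level of genes escaping X inactivation. The mean of 4 such genes was not higher than in BRAF lines 1 and 2 (log2 difference -0.147 in ENSW and -0.048 in base medium, SD 0.073). Xist lay at background on all 20 arrays, so its probes were unproven. EV and selected line 3 kept Y signal (Eif2s3y 0.93 to 1.46). A female or an animal with a single X and no Y would mean a mislabelled line. This and a loss of the Y chromosome in culture stay open, as no test decides.

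Zscan4 and Tcstv genes, which are copies of each other in part and count as 1 signal, had a family mean of -7.01 to -6.19 on EV arrays and -3.68 to -1.61 on BRAF arrays. On selected arrays it was -0.85 and 0.17 for line 1, -6.63 and -5.65 for line 2 and -5.67 and -4.38 for line 3. Arrays of 1 slide and medium differed by 2.36 to 5.82, so slide alone did not set this signal among selected and BRAF arrays. These pairs held no EV array, and EV and BRAF arrays shared no slide. For BRAF against EV organoids slide and organoid type therefore cannot be told apart. All the same, 6 of 6 BRAF arrays lay above the highest EV array, which argued against a single line. In ENSW medium 0 of the 6 genes were called (adjusted p = 0.0821 to 0.446), with a spread that took in the selected lines, which lay far apart. A release of germline genes stays open, since of 25 listed ones 8 were measured and 0 rose in BRAF against EV organoids in either medium, but 16 lay at background on all BRAF arrays, and Rhox5, a germline gene left out of that list, rose in base medium (9.05 ± 1.85, adjusted p = 0.00252). Of 14 genes of the 2-cell embryo, 0 were called in ENSW medium and 6 rose in base medium (5 of the 6 Zscan4 and Tcstv genes, and Dppa4 by 0.81 ± 0.20, adjusted p = 0.00725), Usp17lc fell by 1.21 ± 0.40 (adjusted p = 0.0316), and Zfp352, Tmem92 and 5 others were not called, so these values did not bear out a general programme of that stage and no other one was tested.

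By lists, adjusted p at an estimated correlation stand in brackets. Between BRAF and EV organoids the median difference in response to base medium was 3.42 for proliferation (0.381) and 0.647 for cholesterol synthesis genes (0.631). Between selected and EV organoids it was 4.91 for proliferation (0.49), 0.678 for cholesterol synthesis (0.765) and -2.42 for colonocyte genes (-2.36 with bounds, 0.645). Between selected and BRAF organoids it was 1.35 for proliferation (0.724), -2.11 for colonocyte (-1.87 with bounds, 0.296) and -1.7 for interferon genes (-1.69 with bounds, 0.896). None was called at an estimated correlation.

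By genes, the response differed between BRAF and EV organoids by 4.15 for Mki67, 3.27 for Racgap1, 2.96 for Plk4, 2.53 for Cdca7l, 2.17 for Ska2, -2.67 for Cxcr5, -3.01 for Sntg1, -4.39 for Kynu and -4.53 for Kif27. Between selected and EV organoids it differed by 5.39 for Mki67, 4.51 for Racgap1, 4.45 for Plk4, 3.47 for Ska2, 3.38 for Cdca7l, -2.12 for Spryd7, -2.21 for Lmbrd1, -2.96 for Sntg1 and -3.22 for Cxcr5. Plk4, Ska2 and Cdca7l were not well above background on any EV base array, and Kynu, Kif27, Cxcr5 and Sntg1 were well above background on the 3 EV base arrays and on no array of the other 5 groups, so the sizes of these differences rest on background levels. With normexp the difference between BRAF and EV responses was 0.31 for Plk4 (adjusted p = 0.163), 0.15 for Cdca7l (adjusted p = 0.5), 0.15 for Ska2 (adjusted p = 0.374), -0.26 for Cxcr5 (adjusted p = 0.107) and -0.65 for Kynu (adjusted p = 0.111), 5 lost calls. With the authors' values it was 0.43 for Cdca7l (adjusted p = 0.137) and 0.39 for Ska2 (adjusted p = 0.178), also lost. Between selected and EV responses Sntg1 was lost with normexp (-0.26, adjusted p = 0.0676). Calls that held with normexp shrank as well, to -0.65 for Kif27 and -0.40 for Sntg1 between BRAF and EV responses, and to 0.82 for Plk4, 0.48 for Ska2, 0.36 for Cdca7l and -0.26 for Cxcr5 between selected and EV responses.

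On wild-type arrays Muc2 lay at 4.86 in ENSW and 5.76 in base medium. Braf lay at -2.16 and -2.31 there. In base medium Dusp6 lay at 4.24 and Cdkn2a at 3.47. Each of these lay above the 3 EV arrays of its medium, with 1 wild-type array per medium and no test.

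Splits of each set of 6 arrays into 3 and 3, or of 6 cultures for the responses, number 10 with the real one included, too few for a share under 0.05. In 10 of 12 contrasts 1 split, the real one, gave as many genes. The real count and the highest other were 1346 and 0 (BRAF against EV) and 2967 and 0 (selected against EV) in ENSW medium, 6649 and 1 and 10330 and 1 in base medium, and 130 and 1 and 2096 and 2 for selected against BRAF organoids in ENSW and base medium. For the medium they were 9036 and 13 in EV and 359 and 4 in BRAF organoids, and for the differing responses 750 and 0 against EV in BRAF and 5192 and 0 in selected organoids. For the medium in selected organoids 4 splits gave as many genes, with 1 real and 17 in the highest other, a split that kept the arrays of 2 lines together and so points to the structure between lines. For selected against BRAF responses all 10 gave 0. The other splits that parted all 3 pairs, as the real one did, gave 0 genes in each contrast, and the higher values came from splits that parted 1 pair.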

How the results depend on the processing

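The tests without selected line 1, without BRAF line 3 and those of the lists without 1 array were chosen only after the result was seen. The 12 contrasts kept their counts within 1.5 times under 5 to 13 alternatives each, outside of those named below. BRAF against EV in ENSW medium ranged from 970 to 1905 genes, selected against EV in base medium from 6923 to 10981 and the medium in EV organoids from 8461 to 12513. Of 488 results of named genes, 479 stayed on their side of the threshold with quantile normalization, 435 with normexp, 465 with the authors' values and 458 without a filter, and 0 turned direction. Of 240 list tests, 54 lost a call with an estimated correlation, all but those named in the Results, and 0 gained one. With fry 19 lost and 13 gained one, and with quantile normalization 0 and 4. Of 1800 list tests without 1 array, 31 lost a call, 62 gained one and 1 turned direction (Wnt targets for the medium in selected organoids, adjusted p = 0.38, in a range of 6.89e-07 to 0.782). Quantile normalization also gave a call for fetal-like genes for the medium in selected organoids (0.0265). Beside calls named above, a random slide block gave one for chromatin genes in the response of selected against EV organoids (0.0469). The median of all genes for the medium in EV organoids was 0.19, and 0.085 and 0.029 after quantile and normexp normalization. Genes not well above background give bounds, and a fall below background cannot be sized.

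The other counts were as follows, and the cause was not tested except where fewer arrays or a fold minimum set it. For the medium in BRAF organoids 659 genes were called with normexp (44% higher, against 64.6%), 566 with the authors' values (45.2% higher), 213 without a filter, 725 with slide as a random block, 3 with only the arrays compared and 22 without BRAF line 3. For the response of BRAF against EV organoids they were 1129 with the authors' values, 336 without a filter, 1371 with slide as a random and 176 as a fixed block, 1141 with trend and robust, 11 with only the arrays compared and 179 without BRAF line 3. A fixed slide block gave 414 (ENSW) and 1329 (base) for selected against BRAF organoids and 1 for their responses. A minimum of 2-fold left 627 and 3729 for BRAF against EV in ENSW and base medium, 1464 for selected against EV in ENSW, 1284 for selected against BRAF in base medium and 5479 for the medium in EV organoids. Only the arrays compared gave 776 and 2980 for BRAF against EV, 19 and 232 for selected against BRAF, 0 for the medium in selected organoids and 1 for the response of selected against BRAF organoids. Without selected line 1, 236 genes were called for selected against BRAF in ENSW medium and 2 for the medium in selected organoids, and without BRAF line 3, 964 for selected against BRAF in base medium.

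With the line as a replicate block, 234 genes were called for selected against BRAF in ENSW medium, 616 for the medium in BRAF organoids and 1377 for the response of BRAF against EV organoids. Since both media of a culture are paired, the culture as a random replicate block gave 4078 for the medium in BRAF and 3 in selected organoids, and 4239, 9246 and 335 for the responses of BRAF against EV, selected against EV and selected against BRAF organoids. Apart from the genes and lists named beside their comparisons, the line block changed no other call of a named gene or list.

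Leaving out 1 array in turn gave 372 to 1150 and 4368 to 6715 genes for BRAF against EV (ENSW and base medium), 1131 to 2285 and 8608 to 10007 for selected against EV, 44 to 119 and 840 to 3372 for selected against BRAF, 6623 to 8996, 16 to 1722 and 1 to 1 for the medium in EV, BRAF and selected organoids, and 51 to 1903, 3651 to 5706 and 0 to 1 for the responses of BRAF against EV, selected against EV and selected against BRAF organoids.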

Other observations

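All tests and gene families in this part were chosen only after the result was seen, and their counts are given without a list test. Of 23 genes of drug and steroid metabolism 19 fell and 0 rose in selected against EV organoids in base medium, and 17 fell in ENSW medium. In BRAF against EV organoids 14 fell in base and 6 in ENSW medium, and between the media 11 rose and 1 fell in EV organoids. Ces2c and Ces2e, carboxylesterases, fell by 8.02 ± 0.92 (SE, n = 3 per group, adjusted p = 1.06e-05) and 9.06 ± 1.02 (adjusted p = 9.23e-06) in selected against EV organoids in base medium. Hsd17b2 was at least 1380-fold lower there (adjusted p = 3.32e-11), with 0 of 3 selected arrays well above background. Of 8 genes of bile acid sensing and transport 7 fell in base and 4 in ENSW medium in selected against EV organoids (4 and 2 in BRAF against EV). In base medium the nuclear receptor gene Nr1h4 was at least 352-fold lower (adjusted p = 1.69e-07), with 0 of 3 selected arrays well above background.

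Of 15 genes of antigen presentation 9 fell and 2 rose in selected against EV organoids in base medium, while in ENSW medium 0 fell and 1 rose (H2-DMb1, 5.015 ± 0.86, adjusted p = 0.00256). In base medium H2-K1 fell by 2.72 ± 0.30 (SE, n = 3 per group, adjusted p = 8.19e-06) and B2m by 2.84 ± 0.65 (adjusted p = 0.00231). Cd74 rose by 1.00 ± 0.28 (adjusted p = 0.00815) and H2-DMb1 was at least 13.8-fold higher (adjusted p = 0.000226), with 0 of 3 EV arrays well above background. Between the media 7 of the 15 rose and 0 fell in EV organoids. In base medium 7 fell and 0 rose in BRAF against EV organoids, and 1 and 1 in selected against BRAF organoids. Rhox5 stood at 8.70 and 8.45 on the ENSW and base arrays of BRAF line 2, at 3.76 and 2.17 on those of line 1, at 3.14 and 3.47 on those of line 3 and at -4.65 to -1.04 on the EV arrays. No explanation of these families was tested.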
